A study of Homo sapiens with 2 samples.

How the data were processed

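Total RNA of A549 cells was measured with the nCounter PanCancer Progression panel, per the labels' protocols. The labels give 2 libraries without replicates. The group of each was taken from its treatment label: TGF-β1 (1 library) and TGF-β1 with curcumin (1 library). No library from untreated cells was analysed here. The treatment protocol attached to the TGF-β1 library also names curcumin at 10 and 20 µM, while its title and treatment label do not, so the direction of the comparison rests on the title and the treatment label.

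The deposited values are a normalized signal per probe, held in a table of 770 gene rows and 14 control rows, 6 positive and 8 negative. The normalization software, its version and the reference genes it used are not given in the sources used here. What could be read from the deposited signal is as follows. In the gene rows, each value was a whole count multiplied by one factor per library, 1.59 for TGF-β1 and 0.883 for curcumin. Within a tolerance of 0.0055, 99.9% and 99.8% of the values came out whole. Gene values below the geometric mean of the library's negative control probes had been set to that mean, 1.86 for TGF-β1 and 4.79 for curcumin. This floor held 37 genes with TGF-β1 and 115 with curcumin. The control rows held unscaled counts. All gene names were matched to the RefSeq gene table, 755 as current symbols and 15 through an older symbol.

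Whole counts were recovered by dividing each gene value by its library's factor. They summed to 131309 and 200964, a ratio of 1.53, so the precision is lower in the TGF-β1 library. The most abundant gene took 9.15% of the normalized total with TGF-β1 and 8.14% with curcumin, and the top 10 genes took 37.9% and 35.1%. The background limit, the mean of the negative control probes plus 2 SD, was 7.85 counts with TGF-β1 and 11.7 with curcumin, or 12.5 and 10.3 normalized counts. Both libraries exceeded it for 447 genes. In the TGF-β1 library the negative control probe NEG_F, with 9 counts, lay above the limit itself. The geometric mean of the reference genes was 73.8 and 74.5 normalized counts.

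The comparison was the difference of log2(value + 1) on the deposited scale, curcumin minus TGF-β1. A gene was called measured when the higher of its values was at least 50, and a difference was counted at 1 or more on the log2 scale. With 1 library per group no test across genes was run. Each ratio has an exact conditional binomial (Clopper-Pearson) 95% interval from the recovered counts, without the added 1. It covers counting error only and compares these libraries, not the conditions. By this interval alone, 55 measured genes were higher and 120 lower with curcumin, and so were 2 and 4 of the 21 measured reference genes. For 20 gene lists, the median over measured members was set against 10000 random lists of the same size drawn from measured genes in 10 bins of mean expression. This describes these libraries and is not a test across samples. Lists with fewer than 5 measured members (metalloproteinases, proliferation, endothelial and leukocyte markers) were given no median. The interval of a list's median came from 2000 bootstrap resamples of its members.

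The measure, the filter, the threshold, the gene lists, the rule for named genes and the settings listed next were fixed before the data were examined. The rule took up to 12 genes with the largest positive and 12 with the largest negative differences among those at 2-fold or more. It added 12 EMT readouts whatever their values, and in each list up to 2 measured members with the largest positive and 2 with the largest negative differences. Some genes that the rule names are not reported here. These other settings were pseudocounts of 5 and 20, minimum counts of 20, 100 or none, 3 other scalings (centring on the reference genes, centring on all measured genes, and the same total in both libraries), thresholds of 1.5-fold and 4-fold, the mean in place of the median, and reference genes with at least 100 counts. A pseudocount of 0, subtraction of the negative control mean and the leaving out of single list members were added after seeing the data; the last was chosen before its own values were seen.

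The procedure was tested on simulated data. Counts for the 770 genes were drawn from the real means and library sizes. For the simulated comparison of curcumin with TGF-β1, all measured genes changed 4-fold (27 higher, 21 lower) and 3-fold (29 higher, 18 lower) passed the 2-fold threshold, as did 0 of 248 unchanged genes. In 100 simulated tables without any change, the median number of genes past the threshold was 0 and the highest 2. These tables held counting error only, without variation between cultures or in scaling. They do not give the number of genes expected past the threshold between unchanged cultures. The measured reference genes of the real libraries spread from −0.63 to 0.57. Of 2000 simulated counting intervals, 95.2% held the simulated ratio. A simulated list of 9 members moved by 1 reached percentile 100, again with counting error only. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. GC content and probe sequences were not analysed here.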

Results

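Expression of 770 genes of a cancer progression panel was measured in A549 cells, an established human lung adenocarcinoma line of alveolar epithelial origin. The panel was read on the nCounter platform, in which colour-coded probe pairs are hybridised to RNA and counted one molecule at a time, without amplification. There were 2 libraries, 1 per group: cells given TGF-β1, a cytokine that drives epithelial cells towards a mesenchymal state, and cells given TGF-β1 together with curcumin, a polyphenol of turmeric. Exposure lasted 24 h in both, with 10 ng/mL TGF-β1, and the curcumin library was labelled with 10 µM curcumin. The comparison addressed how the expression of metastasis-related genes differs with curcumin in cells given TGF-β1, a driver of epithelial-mesenchymal transition (EMT). Without a library from untreated cells, neither EMT nor the effect of TGF-β1 itself could be measured here. The total gene count was 131309 in the TGF-β1 library and 200964 in the curcumin library. Neither group had a replicate, so no gene has a replicate check or a p-value. Intervals given here are exact 95% intervals on the ratio of the underlying counts and cover counting error only. Differences are on the scale of log2(normalized count + 1), curcumin library minus TGF-β1 library, which understates the differences of low genes.

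SNAI1, HK2, IL11, ITGA3, LAMA5, ITGA1, CD24, CAV1 and ADAM9 were among the 24 genes that differed by 2-fold or more between the libraries. Of 336 measured genes, those with at least 50 normalized counts in the higher library, 8 were higher with curcumin, 16 were lower and 312 lay in between. SNAI1, a zinc finger repressor of E-cadherin transcription, had the highest ratio among measured genes, with 70.6 normalized counts against 22.3, a 3.17-fold difference (log2 difference 1.62, interval 0.84 to 2.60). HK2, which phosphorylates glucose at the entry of glycolysis, had the lowest, with 22.1 normalized counts against 109.8, and was 4.97-fold lower with curcumin (log2 difference −2.26, interval −3.04 to −1.64). The counting intervals of all 24 genes excluded a ratio of 1, which their choice by these same counts made likely. Among the 21 measured reference genes, 2 intervals also lay above a ratio of 1 and 4 below. The intervals of 5 higher and 10 lower genes lay wholly beyond the range of the measured reference genes, −0.63 to 0.57. All 30 reference genes spanned −0.66 to 0.89, which the lower bounds of SNAI1 (0.84) and WNT5B (0.61) did not exceed. Scaled to the same total, the split was 12 genes higher and 6 lower, among them all 8 of the higher genes and 6 of the 16 lower ones (HK2, LUM, KIAA1462, CHAD, ITGA1 and FBN1).

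**Figure D1:**
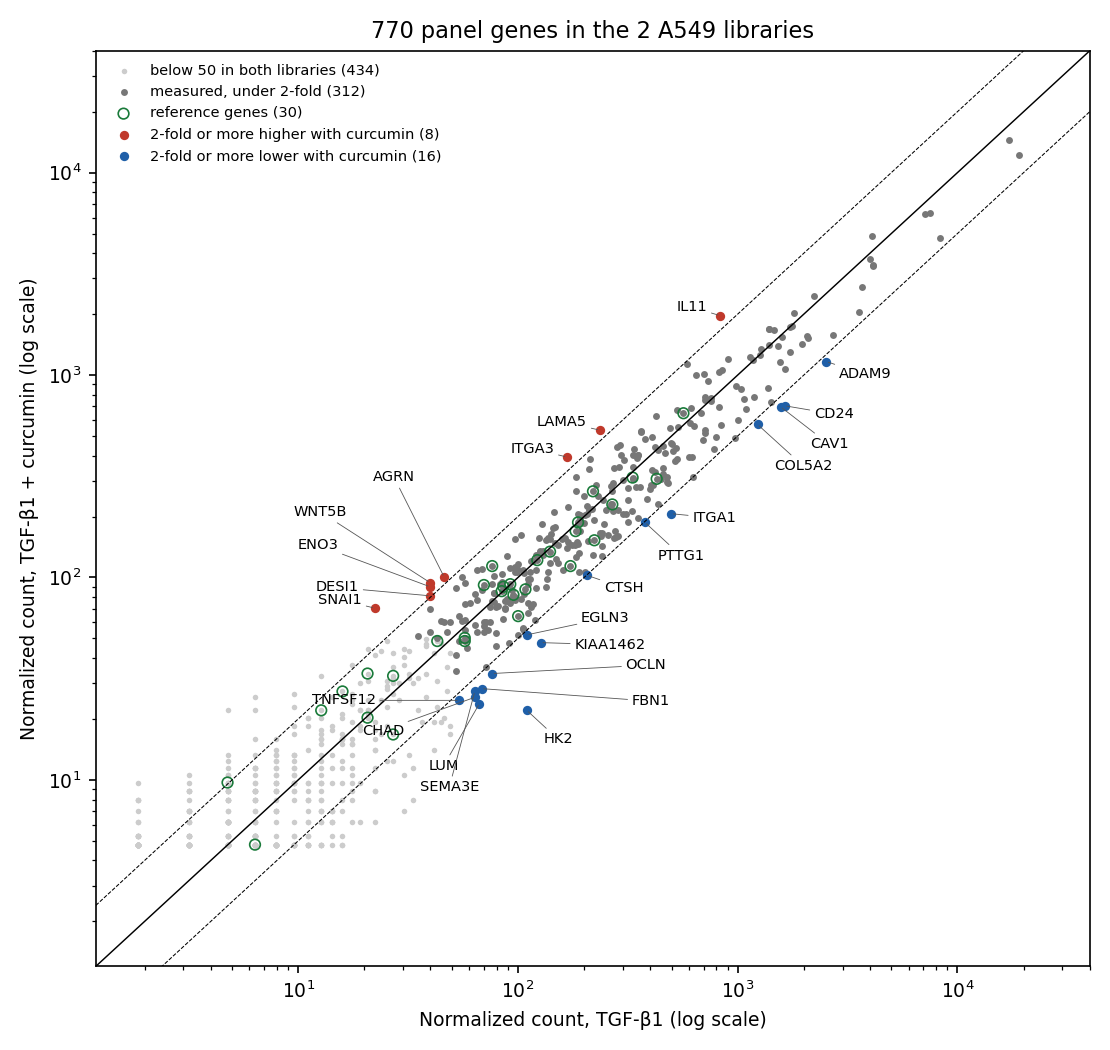
Normalized counts of the 770 panel genes in the TGF-β1 library (x axis) and the TGF-β1 plus curcumin library (y axis), both on log scales. Each point is 1 gene; the solid line marks equal values, the dashed lines a 2-fold difference, red and blue points the 8 higher and 16 lower genes, green rings the 30 reference genes, and pale points the 434 genes below 50 in both libraries.

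Of the other genes higher with curcumin, IL11, a cytokine of the interleukin-6 family, had 1968 normalized counts against 829 (2.38-fold, interval 1.11 to 1.39 on the log2 scale). ITGA3, the alpha chain of a laminin-binding integrin, had 393.7 against 167.0 (2.36-fold, interval 0.93 to 1.56), and LAMA5, a laminin alpha chain, had 534.9 against 235.4 (2.27-fold, interval 0.92 to 1.45). AGRN, a heparan sulfate proteoglycan of basement membranes, had 100.6 against 46.1 (2.18-fold). WNT5B, a Wnt ligand, had 94.5 against 39.8 (2.37-fold), ENO3, the muscle form of enolase, 90.0 against 39.8 (2.26-fold), and DESI1, a peptidase that removes SUMO, 81.2 against 39.8 (2.04-fold). SNAI1, WNT5B, ENO3, AGRN and DESI1 had at most 29 raw counts in the TGF-β1 library. Their lower interval bounds were 0.84, 0.61, 0.54, 0.53 and 0.38 on the log2 scale.

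Of the abundant genes lower with curcumin, ADAM9, a membrane-anchored metalloproteinase, had 1165 normalized counts with curcumin against 2532 (2.17-fold lower, interval −1.23 to −1.01 on the log2 scale). CD24, a small surface glycoprotein, had 705.3 against 1637 (2.32-fold lower), and CAV1, the coat protein of caveolae, had 697.3 against 1567 (2.25-fold lower). COL5A2, a fibrillar collagen chain, had 570.2 against 1231 (2.16-fold lower), and ITGA1, the alpha chain of a collagen-binding integrin, 206.6 against 499.5 (2.42-fold lower, interval −1.52 to −1.03). Scaled to the same total, ITGA1 kept the 2-fold difference at −1.04, while CD24 at −0.98, CAV1 at −0.94, ADAM9 at −0.89 and COL5A2 at −0.88 did not. Less abundant genes were LUM, the matrix proteoglycan lumican (2.80-fold lower), KIAA1462, now named JCAD (2.67-fold lower), CHAD, chondroadherin (2.49-fold lower), and FBN1, fibrillin (2.42-fold lower). SEMA3E, a secreted semaphorin, was 2.33-fold lower and OCLN, occludin of tight junctions, 2.28-fold lower. TNFSF12, a cytokine of the TNF family, was 2.19-fold lower, and EGLN3, a prolyl hydroxylase of hypoxia-inducible factors, 2.11-fold lower. LUM, CHAD, FBN1, SEMA3E, OCLN and TNFSF12 had at most 38 raw counts with curcumin. The upper interval bounds of CHAD, FBN1, EGLN3, OCLN, SEMA3E and TNFSF12 were −0.59, −0.58, −0.55, −0.54, −0.50 and −0.37 on the log2 scale. These did not pass the lowest measured reference gene, at −0.63. The remaining 2 of the 16, PTTG1 and CTSH, both 2.02-fold lower, lay outside the rule for named genes and were chosen after their values were seen.

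Among the EMT readouts fixed in advance, SNAI1 was higher and CDH1, E-cadherin of epithelial junctions, was lower with curcumin. CDH1 had 33.4 normalized counts with TGF-β1 and 7.94 with curcumin, from 21 and 9 raw counts, both under the minimum of 50. The count with curcumin lay below the background limit of 11.7 set by the negative control probes, so no exact ratio is given. With that count raised to 12, just above the limit, the ratio of curcumin to TGF-β1 had an interval of 0.142 to 0.675. The mesenchymal readouts differed less. CDH2, N-cadherin, was at 755.6 against 706.3 (log2 difference 0.10, interval −0.07 to 0.27), and FN1, fibronectin, at 1305 against 1721 (log2 difference −0.40, interval −0.51 to −0.29). VIM, the intermediate filament vimentin, was at 3511 against 4112, a log2 difference of −0.23 that became 0.0039 when the libraries were scaled to the same total. The intervals of SNAI2 (0.38), ZEB1 (0.17), TGFB1 (0.19) and MMP2 (−0.02) all included 0, and so did those of TWIST1 (−0.14) and MMP9 (0.37), which had at most 19 raw counts in either library.

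Of 13 genes on the panel from the EMT transcription factor list, 7 were measured, among them ID1 and ID2, which are inhibitors of DNA binding. Of these, SNAI1 was 2-fold or more higher and none was 2-fold or more lower. Their median log2 difference was 0.17, at percentile 89.4 of 10000 random lists matched on expression. TCF4 was at 0.43, ID2 at −0.33 and SOX9 at −0.20, or 0.03 scaled to the same total. Of 34 mesenchymal markers, 15 were measured: WNT5B was 2-fold or more higher, LUM, FBN1 and COL5A2 were lower, and CD44, the hyaluronan receptor, was at 0.64. Their median of −0.23 lay at percentile 39.99 and became 0.0039 scaled to the same total. Of 35 genes of epithelial adhesion and keratins, 7 were measured, with OCLN lower and none 2-fold or more higher. KRT19 was at 0.54, KRT7 at 0.53 and ELF3, an epithelial transcription factor, at −0.66. The epithelial median of −0.15 lay at percentile 47.98, became 0.07 scaled to the same total, and was −0.58, at percentile 0.80, over the 14 members with at least 20 counts.

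Integrins had the highest median of the 16 gene lists with at least 5 measured members. Of 17 integrin genes, 9 were measured, and their median log2 difference was 0.53, at percentile 99.99, where 95% of matched random lists lay between −0.53 and 0.28. The bootstrap interval of this median over members was −0.20 to 0.71, which includes 0, and the mean was 0.27, at percentile 98.69. ITGA3 was 2-fold or more higher and ITGA1 2-fold or more lower. ITGB3, a chain of the vitronectin receptor, was at 0.71, and ITGB1, the common beta chain, was at −0.20, or 0.03 scaled to the same total. Counting intervals lay above 0 for 6 measured integrins and below 0 for 2. Without a minimum count, the median over all 17 integrins was −0.18, at percentile 21.2.

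Basement membrane and collagen genes went both ways. Of 18 laminin and basement membrane genes, 11 were measured, LAMA5 and AGRN were 2-fold or more higher and none was 2-fold or more lower. FBLN1, fibulin, was at −0.94 and LAMC1, a laminin gamma chain, at −0.67. Their median was 0.03, at percentile 82.9, and their mean 0.22. Of 13 collagens, 7 were measured. COL7A1, the collagen of anchoring fibrils, had 1129 normalized counts against 589 (log2 difference 0.94), COL5A2 was 2-fold or more lower, and COL4A2 was at 0.03. COL18A1 was at −0.19, or 0.04 scaled to the same total. The collagen median of −0.0043 lay at percentile 75.9 and was 0.14 when centred on all measured genes. Of 18 metalloproteinases, only 4 were measured, too few for a median; beside ADAM9 and MMP2, ADAM17 was at 0.33 and ADAM15 at −0.26. Of 13 protease inhibitors and plasminogen system genes, 9 were measured and none differed by 2-fold. PLAUR, the urokinase receptor, was at 0.76, TIMP2 at 0.31, CTSL at −0.34 and TIMP4 at −0.27, with a median of 0.15 at percentile 96.1.

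Genes of TGF-β signalling lay on both sides of 0. Without untreated cells their induction by TGF-β1 was not measured, so a difference shows neither its reversal nor its maintenance. Of 28 TGF-β-induced genes, 23 were measured, with 11 above and 12 below 0; SNAI1 and WNT5B were 2-fold or more higher and none was 2-fold or more lower. BMPR2 was at −0.70 and INHBA at −0.45. The median of −0.0043 lay at percentile 93.9, while the mean was 0.09, so median and mean differed in sign, and the median became 0.23 scaled to the same total. Of 28 TGF-β pathway components, 19 were measured, 6 above and 13 below 0, and none differed by 2-fold. LTBP4, which binds latent TGF-β, was at 0.74 and GDF15 at 0.37. TGFB2, a TGF-β ligand, had 315.1 normalized counts against 625.1 (log2 difference −0.99, interval −1.20 to −0.78), and BMP4, a bone morphogenetic protein, was at −0.95. The median of the pathway list was −0.24, at percentile 21.3.

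NF-κB and inflammatory genes had the lowest of the 16 list medians. Of 24 on the panel, 9 were measured, with a median of −0.66 at percentile 1.86, where 95% of matched random lists lay between −0.60 and 0.28. Its bootstrap interval was −0.76 to 0.44, which includes 0. IL11 was 2-fold or more higher and TNFSF12 2-fold or more lower. TNFRSF12A, the receptor of TNFSF12, was at 0.44 and IL1A, interleukin-1 alpha, at −0.95. The mean over the 9 members was −0.36, at percentile 17.7, and leaving out 1 member at a time gave percentiles between 1.07 and 6.21, outside the random range in 4 of 9 runs. Of 6 genes of the oxidative and proteotoxic stress response, 5 were measured, none differed by 2-fold, and the median was 0.34 at percentile 98.3, with a bootstrap interval of −0.03 to 0.68. HMOX1, haem oxygenase, was at 0.68 (interval 0.18 to 1.23) and HSPB1 at −0.03, or 0.12 centred on all measured genes.

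Hypoxia-induced genes had a median of −0.31 over 14 measured of 16 members, at percentile 12.2, with HK2 and EGLN3 2-fold or more lower and none 2-fold or more higher. VEGFA, vascular endothelial growth factor, had 1692 normalized counts against 1395 (log2 difference 0.28). The VEGF and angiopoietin signalling list also holds PDGF, FGF, Eph, Notch and MET genes. Of its 30 genes on the panel, 12 were measured, none of them an angiopoietin, and none differed by 2-fold. NRP1, a co-receptor of VEGF, was at 0.85, EPHA2 at 0.55, PDGFC at −0.83 and MET, the receptor of hepatocyte growth factor, at −0.62, with a median of 0.12 at percentile 95.2. Of 19 genes listed as endogenous angiogenesis inhibitors, 6 were measured. CHAD, whose part in angiogenesis is not established, was lower. TIMP1 was at 0.11 and ANGPTL4, also on the VEGF list, at −0.26. The median of the 6 was −0.15, at percentile 47.7, or −0.11 without CHAD. Scaled to the same total, the median of the 6 became 0.08. Of 10 actin cytoskeleton and motility genes, 8 were measured and none differed by 2-fold. RHOA, a small GTPase, was at −0.66, its effector ROCK1 at −0.60, PTK2 at 0.29 and RAC1 at 0.13. Their median of −0.14 lay at percentile 49.1 and became 0.0079 centred on all measured genes.

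Markers of other cell types mostly lay below the minimum of 50. None of 18 endothelial markers and 1 of 13 leukocyte markers was measured, the latter SRGN, serglycin, at 0.70. MYC, the only gene of the proliferation list on the panel, was at 0.34.

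**Figure D2:**
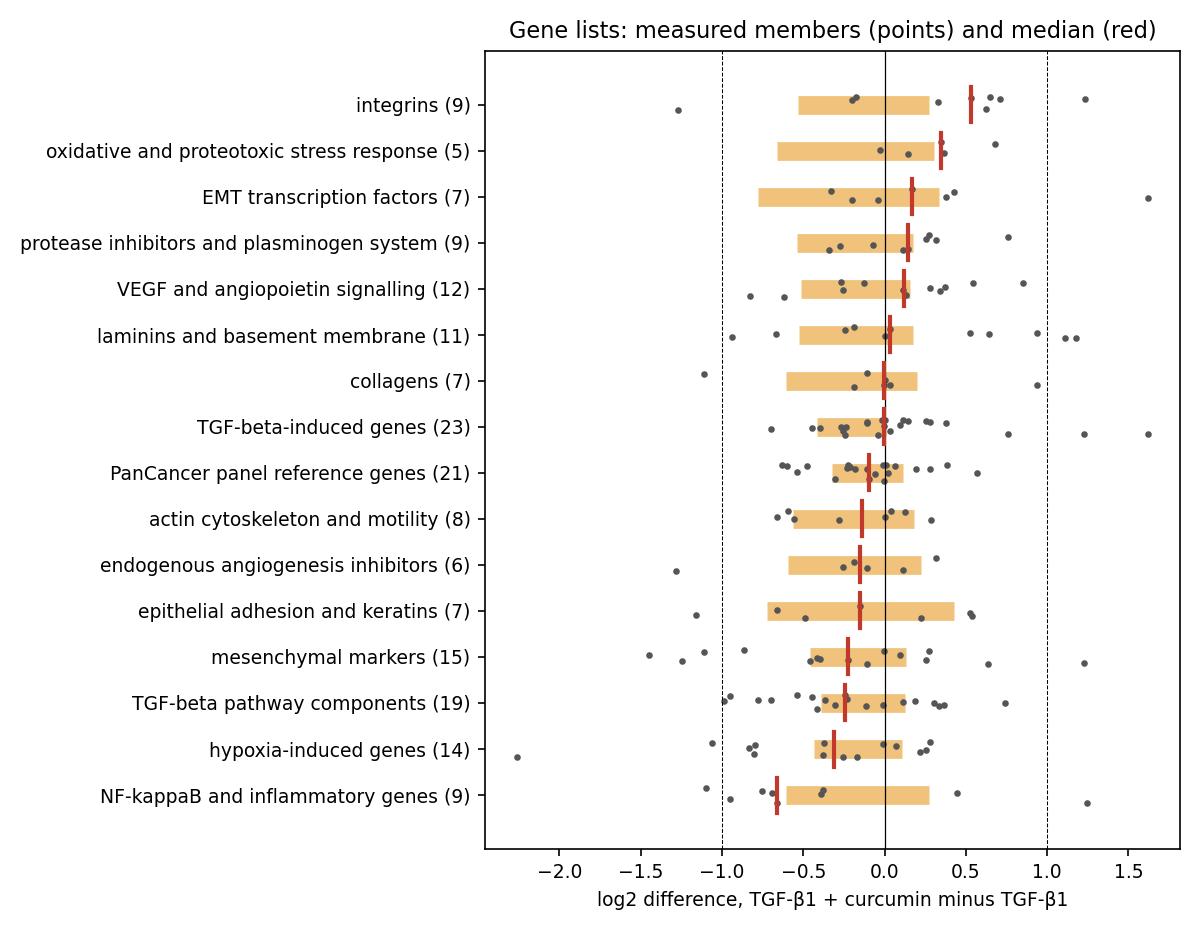
Log2 difference, curcumin library minus TGF-β1 library (x axis), of the measured members of 16 gene lists, with the number of measured members in parentheses. Points are genes, red bars list medians, orange bars the range of 95% of 10000 random lists matched on expression, and dashed lines a 2-fold difference; with the minimum of 50 counts, the integrin and stress medians lie above their ranges and the NF-κB median lies below.

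Of the 16 lists with at least 5 measured members, 3 had medians outside the range of 95% of matched random lists, where 0.8 would be expected by chance if the lists were independent, and they share genes. The bootstrap intervals of all 3 medians include 0. The 30 reference genes of the panel had a median log2 difference of −0.02, from −0.66 to 0.89. The 21 measured among them had a median of −0.09 at percentile 58.0, which became 0.05 centred on all measured genes, with COG7 at 0.57, AGK at 0.39, NUBP1 at −0.63 and ZNF143 at −0.60. Over all 336 measured genes the median was −0.15, with 203 genes below 0, and became 0.08 scaled to the same total. Relative to the median of all measured genes, the integrin, stress and NF-κB medians were 0.68, 0.49 and −0.51. The labels leave open whether the TGF-β1 library was exposed to curcumin: its title and treatment name TGF-β1 alone, while its protocol text also lists 10 and 20 µM curcumin.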

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

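The tests of counting error, background and label order for SNAI1 and CDH1, and of the choice of reference genes, were chosen only after the results were seen; those of the integrins were chosen after their median was seen, but before the tested values were. The control probes stood apart as signal outside the main measurement. The 6 positive control probes summed to 3745 counts in the curcumin library and 1157 in the TGF-β1 library, a ratio of 3.24 (exact 95% counting interval 3.03 to 3.46), against a ratio of 1.72 (1.63 to 1.80) for the summed reference genes. The positive control ratio was 3.51, 3.10, 2.72 and 1.61 for POS_A to POS_D, 3 for POS_E (15 counts against 5) and 3.25 for POS_F (13 against 4). The 8 negative control probes summed to 46 and 20 counts, a ratio of 2.30 (1.33 to 4.10).

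SNAI1 was higher and CDH1 lower in the library labelled curcumin. Counting error is argued against, since the CDH1 ratio had an upper bound of 0.675 with its curcumin count set to the background limit, and the SNAI1 interval lay above 1. Background is argued against too, since in the library where each was higher the lower exact Poisson bound was 13.0 counts for CDH1 and 63.4 for SNAI1, above background limits of 7.85 and 11.7. Swapped labels stay open, because 2 of 5 measured stress genes had counting intervals above 1 and none below, a mixture that decides nothing, and the protocol text does not settle it. Variation between cultures and an effect of curcumin cannot be separated with 1 library per group, so no biological explanation was tested.

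The measured genes were lower on balance with curcumin, with a median log2 difference of −0.15. A response that differs over the count range is argued against as a trend across genes, since the log2 difference and the mean level had a Spearman rho of −0.041 across 336 genes, which are not independent replicates. The positive control ratio did fall from 3.51 to 1.61 between POS_A and POS_D, over 4 probes, and was 3.25 at POS_F. The choice of reference genes for scaling stays open. The median lay inside the bootstrap interval of the measured reference genes, whose lower bound was −0.23 and upper bound 0.0065. That interval also held 0, and the genes used as reference were not varied, so it cannot decide. The shift itself depended on the settings, with a median of 0.08 scaled to the same total and −0.00036 without a minimum, where genes at the floor enter. An effect of curcumin on total RNA per cell was not tested. A uniform one could not show in these scaled values, whose reference gene geometric means were 73.8 and 74.5.

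The measured integrins were higher on balance, with a median of 0.53. Leaving out any 1 of the 9 gave medians between 0.43 and 0.58, at a percentile of at least 99.74. The median thus does not rest on a single member. However, leaving out 1 member moves a median only between neighbouring members, so this check was weak. The mean was not run this way. The level of the genes stays open. The median was above the range of matched random lists under 9 of 10 scaling, pseudocount, background and filter alternatives. However, the scalings, pseudocounts and background subtraction move a percentile little, and it was 99.99 under each. The minimum counts were the main check. The percentile was 99.92 with a minimum of 20 and 99.93 with 100. Without a minimum, where genes near background enter, it was 21.2, inside the range. The abundant members did not all go one way, with ITGB1 at −0.20 (interval −0.25 to −0.15) and ITGA1 at −1.27 (−1.52 to −1.03), and no biological explanation was tested.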

How the results depend on the processing

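Subtraction of the negative control mean, a pseudocount of 0 and the leaving out of single list members were chosen only after the data were seen. Over the 7 alternative pseudocounts, scalings and background settings run for them, 524 of 560 values of named genes stayed within their counting interval and 36 did not, and none of the genes at 2-fold or more changed sign. Genes under 2-fold did: VIM, ITGB1, SOX9, COL18A1, HSPB1, MMP2 and TWIST1 moved from below to above 0 when scaled to the same total.

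The count of 8 genes at 2-fold or more higher with curcumin became 4 with a pseudocount of 20, 16 with a minimum of 20, 4 with a minimum of 100, 66 without a minimum, 23 at 1.5-fold and 0 at 4-fold. The count of 16 lower genes became 7, 31, 10, 53, 66 and 1 under these settings, 10 when centred on all measured genes and 6 when scaled to the same total. Looser minimums and thresholds admit more genes by construction, and those without a minimum include genes at the floor. The floor was 1.86 with TGF-β1 and 4.79 with curcumin. A gene at the floor in both libraries is therefore counted as 2-fold higher with curcumin without any signal, so the 66 is not a result about genes. After subtraction of the negative control mean, 8 genes were higher and 23 lower, including all 8 and all 16.

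Of 173 alternative list medians, 165 stayed within the bootstrap interval. This count leaves out the integrin median without a minimum, which lay inside its interval but changed sign. Scaled to the same total, the medians were 0.23 for TGF-β-induced genes, 0.23 for collagens, 0.77 for integrins, 0.38 for protease inhibitors and 0.14 for reference genes. Centred on all measured genes, those of collagens and reference genes were 0.14 and 0.054. These scalings add one constant to nearly every gene, and so to the random lists as well. They could therefore hardly move a percentile, and runs under them say little about how stable a list's position is. The integrin median turned to −0.18 without a minimum, over 17 genes in place of 9; the cause was not tested further. The NF-κB median lay outside the range of matched random lists in 8 of 11 alternatives and inside it with a pseudocount of 20 (percentile 3.10), a minimum of 100 (6.99) and the mean (17.7), and the stress median in 10 of 10. Lists inside that range left it under 1 alternative each. With a minimum of 20 these were the epithelial list (percentile 0.80) and the VEGF and angiopoietin list (99.5). Under the mean they were TGF-β-induced genes (99.8), laminins (99.3) and hypoxia-induced genes (1.90). Leaving out single members kept integrins outside in 9 of 9 runs and the NF-κB list in 4 of 9, and put laminins outside in 6 of 11 and protease inhibitors in 4 of 9. The stress list was not run this way, since 4 members would remain, and with a minimum of 100 it, the EMT transcription factors and the epithelial list had too few members for a median. The reference gene median was −0.10 over members with at least 100 counts. Fewer than 50 normalized counts in both libraries were found for 434 of 770 genes, and 447 exceeded the background limit in both; low expression was not separated from depth. No paired analysis was possible because each group has 1 library.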

Other observations

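Apart from IL11, the genes in this part were chosen after their values were seen. LDHA, lactate dehydrogenase, had 4776 normalized counts with curcumin against 8334 with TGF-β1 (log2 difference −0.80, exact 95% counting interval −0.86 to −0.75). PGK1, phosphoglycerate kinase, had 1569 against 2725 (log2 difference −0.80, interval −0.89 to −0.70). ENO1 was at −0.17, and PKM and ALDOA lay at 0.01 and 0.07 with intervals that included 0. HIF1A, the alpha subunit of hypoxia-inducible factor, was at 1749 against 1761 (log2 difference −0.0093, interval −0.12 to 0.10). Among cytokines, CXCL8 had 676.1 normalized counts against 1094 (log2 difference −0.69, interval −0.85 to −0.54) and IL6 had 74.2 against 117.7 (log2 difference −0.66, interval −1.14 to −0.20), while IL11 of the same cytokine family as IL6 was higher.

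ITGB4, the partner chain of ITGA6 in hemidesmosomes, had 451.1 normalized counts against 292.7 (log2 difference 0.62, interval 0.38 to 0.87), and ITGA6 was at −0.18 with an interval of −0.51 to 0.16. LAMB3, a laminin beta chain, was at 0.53, HSPG2, perlecan, at 0.64 and VCAN, versican, at 0.67. EGFR was at 0.42, its ligand EREG at 0.75 and its ligand AREG at −0.16 with an interval of −0.69 to 0.37.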
